A study of Mus musculus with 9 samples.

How the data were processed

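Adipose tissue RNA of 9 male C57BL/6J mouse libraries was analysed, 3 in each of the groups CPX, MPX and EA. Libraries were made from total RNA with an Illumina TruSeq RNA kit, per the labels' protocols. Reads were aligned with HISAT2 2.0.5 to the mouse build mm10, per the submitters' processing notes. The counting program, the annotation release and the strand setting are not given in the sources used here. Without a strand setting, reads of overlapping and antisense genes cannot be told apart, and reads of paralogs, of antibody segments and of ribosomal protein pseudogenes could have been split.

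The deposited values are raw counts per gene, 1 column per library, with gene names, positions and lengths, per the file headers. The table used here lists 3958 genes in falling order of their total over the libraries, from 3653827 down to 8471 counts, and its text ends inside the last row. It therefore covers only the most abundant genes, of which 3904 are annotated as protein coding. Genes below that level, among them many list members, were not analysed here. The column sums, 12115183 to 14208853, are not library depths, and CPM values are relative to them after TMM scaling, so they are higher than CPM over a whole library. Each column was matched to its library by the label's title. For 10 genes the name had been turned into a date by spreadsheet software, and for 1 the name was incomplete; these 11 names were restored from the gene ID. Of the gene IDs, 3957 were found in GENCODE M21 and 3802 had the same coordinates there; positions are printed as the authors' table gives them.

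Counts were tested with edgeR 4.0.16 in R 4.3.3. All 9 libraries entered 1 fit with a mean per group, TMM factors (0.753 in CPX 4, and 0.98 to 1.10 in the other 8), filterByExpr and robust quasi-likelihood estimation, and p-values were adjusted after Benjamini-Hochberg over the genes of each of 3 contrasts. The filter removed no gene (3958 kept), nor did a filter of 1 CPM in 3 libraries, so filter alternatives say nothing about stability. The common dispersion was 0.161, a biological coefficient of variation of 40.1%. Log2 differences are those of the fit, and their SE was taken as the difference divided by the square root of F. No batch is given in the labels, and each comparison used only label groups. No pair of libraries in a group held near-identical counts: the chi-square per degree of freedom between replicates was at least 71.5 (MPX 5 and MPX 7).

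Before the data were examined, 40 gene lists (metabolic pathways, signalling, cell types of fat and of tissues that could be mixed in), the tests, the alternatives and the rule for named genes were fixed. Of these lists 31 had at least 3 listed members and were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Another 2 lists had 1 or 2 members and 7 had none, and they were not analysed here. Camera with an estimated correlation and fry served as alternatives; fry asks whether a list moves one way on balance and does not compare it with other genes. With 3 libraries against 3, an exact permutation test of a single value cannot give a two-sided p below 0.1.

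The rule for named genes was as follows. In each contrast, among genes past the adjusted p threshold with a proper symbol, a mean of at least 50 counts and ranges that do not overlap, the 12 largest rises and 12 largest falls were to be named, leaving out antibody and T cell receptor segments. Where fewer than 10 genes passed, as in all 3 contrasts, the 10 genes with the smallest p and a proper symbol were taken and named as not past the threshold. In each list that passed, up to 4 members with the smallest p were taken, of which the text gives some. Some of the members so taken are not reported here singly, and no others took their place. A further 12 genes were fixed for every contrast, of which 8 are listed.

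The method was tested on simulated counts drawn with the means, library sizes and spread of these 9 libraries, with 200 of 3958 genes changed. For EA against MPX, edgeR recovered 8.96% of the 2-fold changes, 68.7% of the 4-fold changes and 90.9% of the 8-fold changes, with 5 false calls. The changed genes were drawn at random from all listed genes. On the real counts the same test called 0 genes, and even Pax5, at 151.8-fold, did not pass (edgeR adjusted p = 0.775). These shares therefore do not hold for genes that vary between libraries as Pax5 does. A list raised 2-fold had the smallest p of 31 lists, and 0 other lists were called. Those simulations drew genes independently, so they do not test a list whose members vary together. The alternatives were other scalings, filters, DESeq2 1.42.0, limma voom, the robust option off, only the groups compared, a minimum fold of 2, each library left out, and number as a block. The DESeq2 calls in 100 simulations of unchanged groups, drawn the same way without changed genes, were added after its calls were seen. With genes drawn independently, they do not bound the calls where genes vary together between libraries.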

Results

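RNA sequencing was used to measure gene expression in adipose tissue of male C57BL/6J mice at day 21. C57BL/6J is a common inbred mouse strain that gains fat on a high-fat diet. The series design names mice on a normal diet, mice on a high-fat diet, and mice on a high-fat diet that received electroacupuncture, in which a current is passed through acupuncture needles. The labels place 3 libraries in the electroacupuncture group (EA, numbers 5, 7 and 8). The other 6 libraries carry the title prefixes CPX (numbers 4, 6 and 8) and MPX (numbers 2, 5 and 7). The labels do not say which prefix stands for which diet, so both prefixes are kept here and no difference is given a diet direction. The fat depot is not stated, and the extraction protocol in the labels speaks of retinas although the tissue is labelled adipose. The 18 retina genes of a list fixed beforehand were not analysed here, since none was among the listed genes.

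The counts cover 3958 genes, the most abundant ones in these libraries, and the listed counts per library ran from 12115183 (CPX 6) to 14208853 (MPX 7). These totals are sums over the listed genes and not sequencing depths. Every gene had at least 8471 counts over the 9 libraries, but single libraries could hold few: Pax5, a B cell gene, was at 0.42 CPM in MPX 7, where counting error adds to the spread between libraries. Levels are given as CPM, scaled to the listed counts, with the SD over 3 libraries. The labels do not say that each library came from a separate mouse, so the p-values measure the spread between these libraries.

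The 3 CPX libraries differed from each other more than the libraries of the other groups did. Spearman's correlation across genes was 0.19 between CPX 4 and CPX 6, 0.31 between CPX 6 and CPX 8, and 0.72 between CPX 4 and CPX 8. Within MPX it was at least 0.87, and within EA at least 0.79; genes are not independent replicates. CPX 6 correlated best with EA 8 (0.74). CPX 6 was rich in B cell transcripts, with 489 CPM of Cd79a, a B cell receptor component, against 2.37 CPM in CPX 4 and 4.96 CPM in CPX 8. Its 18 listed adipocyte identity genes stood on average 2.03 below their mean over the 9 libraries on the log2 scale. CPX 4 held more mitochondrially encoded transcripts than every other library (10 genes, 2.02 above their mean on the log2 scale).

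Adipose tissue after electroacupuncture was first compared with MPX, one of the groups without it. The labels do not say whether MPX had the high-fat diet of EA, so the groups may also differ in diet. The clearest difference lay in genes of antibody-making cells and B cells, which apart from Ighm, an antibody heavy chain gene, stood at low levels in MPX. Jchain, which joins antibody chains into multimers, averaged 198.7 ± 129.4 CPM in EA and 2.99 ± 1.92 CPM in MPX (SD, n = 3 in each group), a log2 difference of 6.05 (SE 1.07). Cd79a averaged 154.3 ± 73.0 CPM in EA against 1.92 ± 1.44 CPM in MPX, and Pax5, a B cell transcription factor, 117.1 ± 65.4 CPM against 0.77 ± 0.48 CPM. In the other direction, Lep, the fat-derived satiety hormone leptin, averaged 787.5 ± 575.4 CPM in EA and 4369 ± 2801 CPM in MPX. Hmgcs1, an enzyme of cholesterol synthesis, averaged 131.3 ± 46.5 CPM against 455.4 ± 83.8 CPM. No single gene passed the test: with edgeR's quasi-likelihood test on all 9 libraries, 0 of 3958 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.775. At an unadjusted p under 0.05 there were 202 genes (5.10%), 83 higher and 119 lower in EA. DESeq2 called 49 genes (21 higher, 28 lower) and limma voom 0. In 100 simulations of unchanged groups DESeq2 called 16.9 genes on average (at most 38). The simulated genes varied independently, so these counts do not bound the calls of unchanged groups whose genes vary together. The call depended on the CPX libraries, which share the estimate of the spread: with EA and MPX alone, edgeR called 84 genes (62 higher, 22 lower), and without CPX 6 it called 23.

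Of the 62 genes higher in EA in the fit of EA and MPX alone, 9 belonged to the 11 listed genes of the B cell and lymph node list. Of the same 62 genes, 51 were at least 4-fold higher in CPX 6 than the mean of CPX 4 and CPX 8, as were 0 of the 22 lower genes and 229 of all 3958, so most of the higher genes were also high in a library without electroacupuncture. Among the 9 B cell genes, Cr2, a complement receptor of B cells and follicular dendritic cells, had a log2 difference of 7.37 (SE 0.62, edgeR adjusted p = 0.0104). Among the 22 lower genes, Col15a1 (log2 difference -1.80, edgeR adjusted p = 0.0447) and Lox (-1.35, edgeR adjusted p = 0.0478) encode a basement membrane collagen and a collagen-crosslinking enzyme. With the mean level of 10 B cell genes as a covariate on all 9 libraries, Lox turned to 0.58 and Cr2, itself a B cell gene, to -0.026. That mean did not overlap between EA (6.29 to 7.99 on the log2 scale) and MPX (0.02 to 1.23), so the adjustment rests largely on CPX 6 (8.85). Alcam, a cell adhesion molecule, was lower in the fit of EA and MPX alone (-1.63, edgeR adjusted p = 0.0288), but did not pass with the covariate (-1.33), with 40.6 ± 3.03 CPM in EA and 122.5 ± 34.3 CPM in MPX. The genes for Jchain (mm10, chromosome 5, 88519809 to 88527891, minus strand) and Alcam (chromosome 16, 52248996 to 52454074, minus strand) are both annotated as protein coding. Antibody genes such as Ighg2b have close relatives whose reads the counting could split, so their values are uncertain.

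Taken list by list over all 9 libraries, 10 of 31 tested gene lists differed between EA and MPX by camera with a preset correlation (6 higher, 4 lower). All 11 listed B cell genes had positive differences (median log2 difference 6.33, adjusted p = 2.76e-13), and 10 of them passed when adjusted over the list alone. All 6 class II antigen presentation genes had positive differences (median 1.2, adjusted p = 0.000227), led by H2-Ob at 105.6 ± 50.5 CPM against 2.56 ± 0.70 CPM. All 3 listed mast cell genes, Cpa3, Cma1 and Mcpt4, which encode mast cell proteases, had positive differences (median 2.16, adjusted p = 1.13e-05), and all 3 passed when adjusted over the list alone. Mcpt4 averaged 167.5 ± 66.5 CPM in EA and 37.6 ± 33.2 CPM in MPX. All 14 macrophage genes had positive differences (median 0.65, adjusted p = 4.43e-05), with Timd4, a receptor of resident macrophages, at 82.8 ± 20.7 CPM against 4.16 ± 2.58 CPM and Lyve1 at 170.9 ± 57.2 CPM against 45.6 ± 15.8 CPM. All 45 ribosomal protein genes had positive differences (median 0.76, adjusted p = 3.87e-12), and 10 of 12 endoplasmic reticulum stress genes did (median 0.54, adjusted p = 0.00437). In the class II, macrophage, ribosomal and stress lists 0 genes passed when adjusted over the list alone. With an estimated correlation none of these calls held: adjusted p = 0.386 for the B cell and mast cell lists and adjusted p = 0.628 for the other 4. With the mean level of 10 B cell genes as a covariate, H2-Ob turned to -0.45, and of the macrophage genes Siglec1 turned to -0.092 and Lyz2 to -0.44. Timd4 was also high in CPX 6 (372.2 CPM), and the macrophage list was higher in MPX 2 (0.44) than in EA 7 (0.27).

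Lower in EA were the immediate early genes, which respond within minutes to stimuli: 10 of 10 had negative differences (median -0.56, adjusted p = 7.81e-06), and 4 passed when adjusted over the list alone. Egr1 averaged 27.4 ± 8.17 CPM in EA and 198 ± 150.1 CPM in MPX, and Dusp1 94.2 ± 23.3 CPM against 226.3 ± 39.2 CPM. All 9 fat mass expansion genes, which in mice are known to track the growth of fat stores, had negative differences (median -1.44, adjusted p = 1.39e-05), among them Lep and Mest (54.0 ± 81.3 CPM against 712.9 ± 602.7 CPM). Of 25 extracellular matrix genes 18 had negative differences (median -0.49, adjusted p = 0.000395), with Col4a2 at 617 ± 91.5 CPM against 1657 ± 505.8 CPM and Sparc at 1950 ± 388.1 CPM against 5270 ± 1240 CPM. All 12 endothelial genes had negative differences (median -0.42, adjusted p = 0.00437), with Cldn5, a tight junction protein, at 116.4 ± 47.1 CPM against 266.1 ± 95.4 CPM. In the fat mass, matrix and endothelial lists 0 genes passed when adjusted over the list alone, and with the mean level of 10 B cell genes as a covariate Lep (0.51) and Sparc (0.40) turned direction. With an estimated correlation these calls were lost as well: adjusted p = 0.386 for the immediate early list and adjusted p = 0.628 for the other 3. The number of camera calls with a preset correlation was also not particular to the groups, since the 9 other splits of these 6 libraries gave between 10 and 18 lists. Those splits mix EA with MPX and count lists without regard to which, so they do not test a single call. The extracellular matrix call was lost without MPX 2 (adjusted p = 0.0752), and the endothelial call without MPX 5 (adjusted p = 0.0626). The endoplasmic reticulum stress call was lost without EA 8 (adjusted p = 0.168), with EA and MPX alone (0.0799), and with CPX 4 and 6 left out (0.0805).

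**Figure D1:**
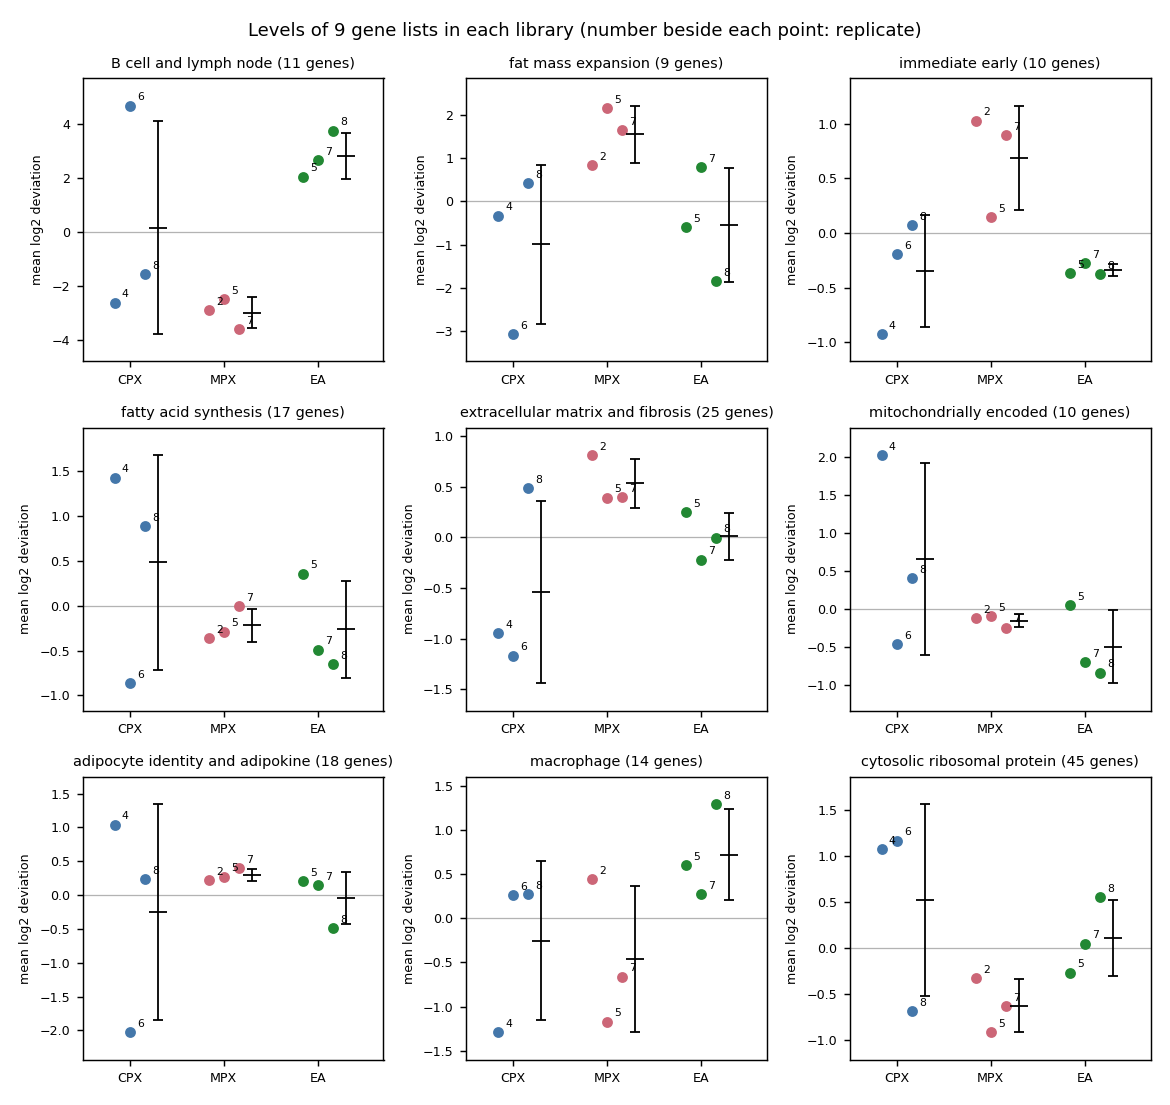
Mean log2 deviation of 9 gene lists in each library from each gene's mean over the 9 libraries, with 1 point per library, its replicate number beside it, and group mean ± SD (n = 3) in black. The 3 EA libraries and CPX 6 lie above 2.0 in the B cell list, while the other 5 libraries lie below -1.5.

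MPX was then compared with CPX, the groups without electroacupuncture, which by the design text differ in diet. The 10 genes with the smallest p, none past the threshold, included Jchain, Adcy5, Pltp and Elovl6. Elovl6, which elongates newly made fatty acids, averaged 27.9 ± 10.4 CPM in MPX and 208.4 ± 119.6 CPM in CPX, a log2 difference of -2.90 (SE 0.59, SD over n = 3 in each group). Acly, which supplies the acetyl units for fat synthesis, averaged 313 ± 59.8 CPM in MPX against 1188 ± 742.7 CPM in CPX. Pltp, the phospholipid transfer protein, averaged 648.5 ± 76.7 CPM in MPX against 140.8 ± 79.6 CPM in CPX, a difference of 2.20 (SE 0.41), and Adcy5, an adenylyl cyclase, 379.4 ± 20.3 CPM against 90.7 ± 40.6 CPM, a difference of 2.06 (SE 0.36). Jchain was at 2.99 ± 1.92 CPM in MPX and 694.9 ± 740.3 CPM in CPX, and its lowest CPX value, 196.5 CPM in CPX 4, still lay above all MPX values. Elovl6 lies on chromosome 3 (mm10, 129532355 to 129638495, plus strand) and Pltp on chromosome 2 (164839518 to 164857711, minus strand). By edgeR's test 0 of 3958 genes passed (smallest adjusted p = 0.362), and 522 genes (13.2%) had an unadjusted p under 0.05, 197 higher and 325 lower in MPX. DESeq2 called 201 genes (69 higher, 132 lower), among them Elovl6 (DESeq2 adjusted p = 3.17e-05) and Pltp (DESeq2 adjusted p = 1.01e-05), and limma voom called 0; in simulated unchanged groups DESeq2 called 16.4 genes on average (at most 44). Without CPX 8, edgeR called 168 genes.

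By camera with a preset correlation, 15 of 31 lists differed between MPX and CPX, 8 higher and 7 lower in MPX. All 17 fatty acid synthesis genes had negative differences (from -2.90 to -0.0059, median -0.99, adjusted p = 0.00141), and 1, Elovl6, passed when adjusted over the list alone. The 45 ribosomal protein genes all had negative differences (median -1.32, adjusted p = 3.08e-20), 29 of them past the threshold when adjusted over the list alone; Rps6 averaged 390.5 ± 78.1 CPM against 1375 ± 799.6 CPM. The 10 mitochondrially encoded genes all had negative differences (median -1.01, adjusted p = 0.00656), with mt-Co1 at 16940 ± 816.2 CPM against 36510 ± 26690 CPM. The 11 B cell genes (median -6.35, adjusted p = 7.12e-05), the 3 mast cell genes (median -1.66, adjusted p = 0.00672) and the 6 class II genes (median -1.53, adjusted p = 0.0272) all had negative differences too. Among the B cell genes 11 passed when adjusted over the list alone, but Cd79a, Cd79b and Pax5 overlapped between the groups, because of their 3 CPX libraries only CPX 6 was high. Of 12 endoplasmic reticulum stress genes, 10 had negative differences (median -0.43, adjusted p = 0.0391), such as Herpud1 at 92.5 ± 2.11 CPM in MPX against 162.3 ± 36.3 CPM in CPX. In the mitochondrial, mast cell, class II and stress lists 0 genes passed when adjusted over the list alone. With an estimated correlation these calls were lost: adjusted p = 0.565 for the ribosomal and mast cell lists, adjusted p = 0.733 for the B cell list and adjusted p = 0.816 for the other 4. Without CPX 6 the B cell (adjusted p = 0.126), class II (0.941), mast cell (0.0638) and stress (0.0942) calls were lost, and without CPX 4 the mitochondrial (0.639), fatty acid synthesis (0.263) and stress (0.0784) calls. Without CPX 8 the fatty acid synthesis (adjusted p = 0.0983), mast cell (0.0812) and stress (0.121) calls were lost, and without MPX 2 the stress call (0.0586). The ribosomal list lay at 1.07 in CPX 4 and 1.16 in CPX 6, but at -0.69 in CPX 8, beside the MPX mean of -0.63. With CPX 4 and 6 left out, which leaves CPX 8 alone in its group and its spread assumed like that of the other groups, the ribosomal list turned direction (adjusted p = 0.498), and the class II (0.319) and stress (0.188) calls were lost.

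Positive differences in MPX minus CPX were found for 23 of 25 extracellular matrix genes (median 0.79, adjusted p = 9.76e-09), with Thbs1 at 241.9 ± 85.6 CPM against 57.8 ± 33.4 CPM and Postn at 329.1 ± 90.7 CPM against 176.4 ± 46.3 CPM. Of 9 fat mass expansion genes 8 had positive differences (median 1.79, adjusted p = 3.98e-05): Lep averaged 4369 ± 2801 CPM against 772.8 ± 632.2 CPM, and Sfrp5 489 ± 272.5 CPM against 37.5 ± 48.2 CPM. All 10 immediate early genes had positive differences (median 0.81, adjusted p = 3.98e-05), and so did 11 of 12 endothelial genes (median 0.59, adjusted p = 7.12e-05). Positive differences were also found for 16 of 19 fatty acid oxidation genes (median 0.38, adjusted p = 0.00379), led by Cpt1a, the carnitine transferase that admits fatty acids to mitochondria. The same held for 11 of 15 lipolysis and lipid droplet genes (median 0.57, adjusted p = 0.00379) and 12 of 14 triglyceride genes (median 0.54, adjusted p = 0.00672). Among 12 lipid-associated macrophage genes, 8 had positive differences (median 0.49, adjusted p = 0.0095), with Gpnmb at 258.1 ± 187.1 CPM against 47.2 ± 39.0 CPM and Lgals3 at 295 ± 125.6 CPM against 103.2 ± 27.6 CPM. In these 8 lists 0 genes passed when adjusted over the list alone. With an estimated correlation the adjusted p was 0.565 for the matrix, fat mass, immediate early, endothelial and lipid-associated macrophage lists, and adjusted p = 0.816 for the other 3. Other splits of the 6 libraries gave up to 21 lists, and without CPX 6 the triglyceride list turned direction (adjusted p = 0.951). Without CPX 6 the lipolysis (adjusted p = 0.902), fatty acid oxidation (0.723) and lipid-associated macrophage (0.0561) calls were lost, the last also without CPX 8 (0.106) and MPX 2 (0.111). The matrix list lay at -0.95 in CPX 4 and -1.17 in CPX 6, but at 0.49 in CPX 8, within the MPX range of 0.39 to 0.81. Against CPX 8 alone, with CPX 4 and 6 left out, the matrix and endothelial (both adjusted p = 0.583), fat mass (0.0867), lipolysis (0.0895) and triglyceride (0.252) calls were lost.

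**Figure D2:**
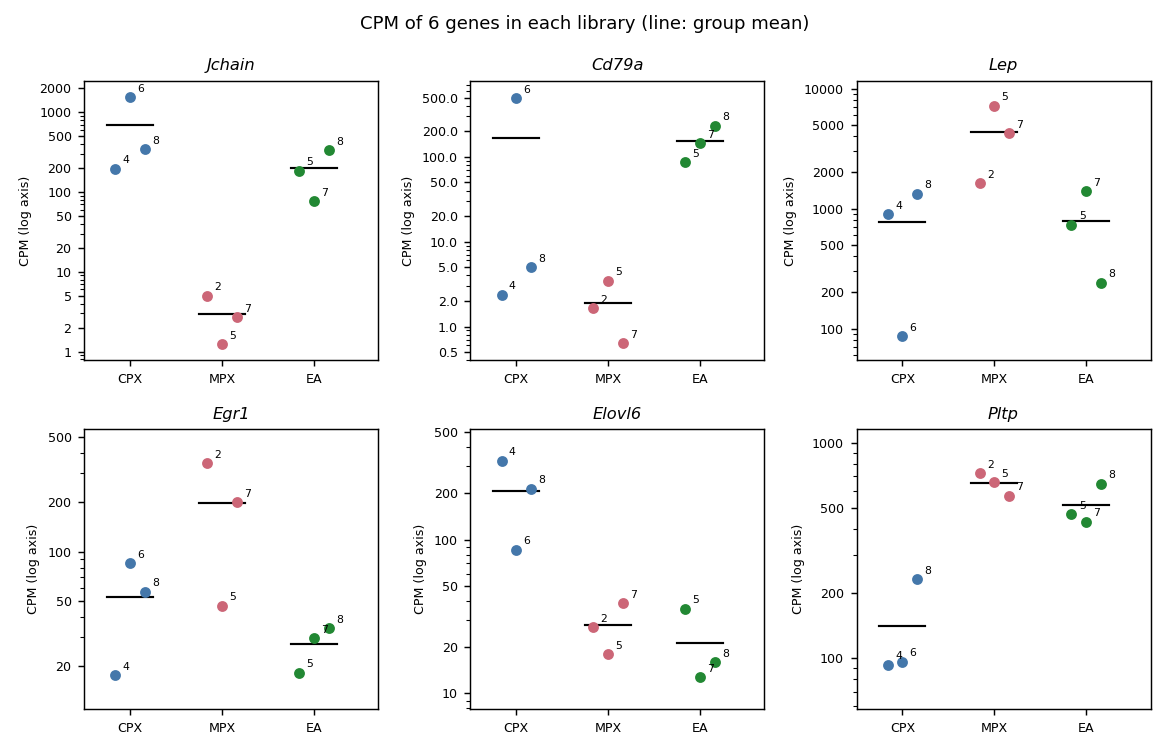
CPM of Jchain, Cd79a, Lep, Egr1, Elovl6 and Pltp on log axes, with 1 point per library, its replicate number beside it, and a line at each group mean (n = 3). Elovl6 lies at or above 86.1 CPM in the 3 CPX libraries and at or below 38.8 CPM in the other 6, and Pltp at or below 232.7 CPM in CPX and at or above 430 CPM elsewhere.

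EA was finally compared with CPX, which may likewise differ from EA in diet. Elovl6 averaged 21.4 ± 12.4 CPM against 208.4 ± 119.6 CPM in CPX, a log2 difference of -3.28 (SE 0.60, SD over n = 3 in each group), and Scd2 240.4 ± 91.7 CPM against 588.3 ± 135 CPM. Pltp averaged 513.8 ± 115.8 CPM in EA against 140.8 ± 79.6 CPM (difference 1.87, SE 0.41), and Adcy5 249.4 ± 66.6 CPM against 90.7 ± 40.6 CPM (difference 1.46, SE 0.35). Noct, a gene with a daily rhythm, was at 79.7 ± 22.0 CPM against 33.6 ± 10.5 CPM, and Pdk1, a kinase that restrains pyruvate oxidation, at 61.2 ± 5.30 CPM against 128.9 ± 43.1 CPM. Vcp-rs was at 65.4 ± 8.0 CPM against 112.3 ± 10.4 CPM, and it is uncertain because it is a copy related to Vcp. No gene passed edgeR's test (0 of 3958, smallest adjusted p = 0.997), and 117 genes (2.96%) had an unadjusted p under 0.05, 38 higher and 79 lower in EA. DESeq2 called 5 genes: Elovl6, Vcp-rs, Pltp, Adcy5 and Tmem30a, the last named after its values were seen; in simulated unchanged groups it called more, 16.6 on average (at most 33). Limma voom called 0, and edgeR without CPX 6 called 12 genes (11 higher, 1 lower).

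By camera with a preset correlation, 12 of 31 lists differed between EA and CPX, 7 higher and 5 lower in EA. The 10 mitochondrially encoded genes all had negative differences (median -1.28, adjusted p = 2.71e-09), with mt-Nd5 at 2739 ± 665 CPM against 5981 ± 2495 CPM, and so had the 45 ribosomal protein genes (median -0.64, adjusted p = 2.44e-07). Of 17 fatty acid synthesis genes 15 had negative differences (median -1.10, adjusted p = 1.38e-05), and 1, Elovl6, passed when adjusted over the list alone. The same direction was seen for 62 of 63 respiratory chain genes (median -0.51, adjusted p = 3.32e-05) and for the 3 listed Schwann cell genes (median -1.01, adjusted p = 0.0373), among them Mbp at 96.7 ± 7.04 CPM against 195.3 ± 85.8 CPM. Mitochondrial and respiratory chain transcripts were highest in CPX 4, and without that library the respiratory chain list turned direction (adjusted p = 9.39e-11). The mitochondrially encoded call was kept without CPX 4 and in every other fit with a single library left out. Positive differences were found for 13 of 14 macrophage genes (median 0.60, adjusted p = 1.12e-05), among them Cd68 at 155.5 ± 83.4 CPM against 62.4 ± 42.2 CPM. Gpnmb, at 231.1 ± 182.5 CPM against 47.2 ± 39.0 CPM, led the lipid-associated macrophage list (8 of 12 positive, median 0.16, adjusted p = 0.0218). Without CPX 4 the fatty acid synthesis (adjusted p = 0.24), ribosomal (0.0889), macrophage (0.0889) and Schwann cell (0.105) calls were lost, and without CPX 6 the ribosomal (0.449) and lipid-associated macrophage (0.562) calls. Without CPX 8 the fatty acid synthesis (adjusted p = 0.0706), lipid-associated macrophage (0.189) and Schwann cell (0.729) calls were lost, without EA 8 the lipid-associated macrophage (0.207) and Schwann cell (0.0744) calls, and without EA 7 the Schwann cell call (0.052). Against CPX 8 alone, with CPX 4 and 6 left out, the macrophage and lipid-associated macrophage calls were lost (both adjusted p = 0.321), and the respiratory chain (0.198) and ribosomal (2.44e-13) lists turned direction. Apart from Elovl6, 0 genes of these 7 lists passed when adjusted over the list alone. With an estimated correlation the adjusted p was 0.767 for the respiratory chain list and 0.718 for the other 6 lists named here.

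Further lists higher in EA than in CPX were extracellular matrix (17 of 25 positive, median 0.15, adjusted p = 9.31e-05), with Postn at 334.9 ± 108.3 CPM against 176.4 ± 46.3 CPM, and fatty acid oxidation (17 of 19 positive, median 0.22, adjusted p = 0.00449). The endothelial list (9 of 12 positive, median 0.26) and the lipolysis and lipid droplet list (11 of 15 positive, median 0.19) both had an adjusted p = 0.0373. The B cell list was called higher (adjusted p = 0.0259) although its median log2 difference was -0.10 and its mean -0.24, with 5 of 11 genes positive; its median was positive with upper-quartile factors (0.03) and limma voom (2.85). Without CPX 6 its adjusted p was 1.03e-19, and Ighd, the heavy chain of IgD, turned from -1.12 to 6.17 (edgeR adjusted p = 0.0235). Upper-quartile factors moved the median of all genes in this comparison from -0.09 to 0.03. In these 5 lists 0 genes passed when adjusted over the list alone, and with an estimated correlation the calls were lost, with adjusted p = 0.767 for the lipolysis list and adjusted p = 0.718 for the other 4. Other splits of these 6 libraries gave up to 22 lists. Without CPX 6 the fatty acid oxidation (adjusted p = 0.589), endothelial (0.956) and lipolysis (0.136) lists turned direction and the matrix call was lost (0.589). Without CPX 4 the B cell (adjusted p = 0.886), matrix (0.0889) and endothelial (0.135) calls were lost, and without CPX 8 the B cell (0.52), fatty acid oxidation (0.0706) and lipolysis (0.0706) calls. The fatty acid oxidation (adjusted p = 0.579) and lipolysis (0.234) calls were also lost without EA 5, the endothelial (0.297) and lipolysis (0.0787) calls without EA 7, and the B cell call without EA 8 (0.244). Against CPX 8 alone, with CPX 4 and 6 left out, the fatty acid oxidation call was lost (adjusted p = 0.294), and the matrix (0.000494), endothelial (0.0824) and lipolysis (0.70) lists turned direction.

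Several genes were to be reported whatever their values. Adipoq, the adipocyte hormone adiponectin, averaged 2694 ± 2535 CPM in CPX, 2916 ± 362.8 CPM in MPX and 1841 ± 284.5 CPM in EA. Pparg, the master regulator of fat cell formation, averaged 321.2 ± 267.6, 248.8 ± 18.2 and 178.6 ± 42.0 CPM in the same order, and Slc2a4, the insulin-regulated glucose transporter, 262.8 ± 205.9, 264.5 ± 37.9 and 241.9 ± 68.7 CPM. Fasn, fatty acid synthase, averaged 8444 ± 5437 CPM in CPX, 3062 ± 849.9 CPM in MPX and 3382 ± 2889 CPM in EA. Scd1, a fatty acid desaturase and the most abundant listed gene in most libraries, averaged 39580 ± 25120, 38350 ± 4659 and 15980 ± 12200 CPM. Adgre1, a macrophage surface marker, averaged 65.8 ± 34.2, 106.3 ± 85.7 and 146 ± 102 CPM, and Col1a1, a fibrillar collagen, 660.7 ± 582.8, 1316 ± 866.7 and 1077 ± 455.9 CPM. Lep on chromosome 6 (mm10, 29060220 to 29073877, plus strand) averaged 772.8 ± 632.2, 4369 ± 2801 and 787.5 ± 575.4 CPM, all with n = 3. None of these 8 genes passed edgeR's test in any of the 3 comparisons; for Lep the edgeR adjusted p was 0.775 for EA against MPX, 0.374 for MPX against CPX and 0.999 for EA against CPX. With the mean level of 10 B cell genes as a covariate, Adipoq (2.19), Pparg (2.14) and Slc2a4 (2.47) turned to positive differences past the threshold in EA against MPX, as did Adipoq (1.49), Pparg (0.98) and Slc2a4 (1.66) in EA against CPX. These sign changes rest largely on CPX 6, since that mean did not overlap between EA and MPX. Ucp1, Itgax, Trem2 and Ccl2 were not analysed here.

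The last question was whether EA libraries lie back toward CPX for genes that differ between MPX and CPX. Across the 3958 genes, the log2 differences EA minus MPX and MPX minus CPX correlated negatively (Pearson r = -0.80, covariance -0.445). Both contain the MPX libraries, so simulated unchanged groups also gave a negative value, on average r = -0.50 (range -0.57 to -0.44 in 100 simulations) with covariance -0.130. The covariance exceeded the simulated one by -0.315. Much of the opposition rested on CPX 6: without it r was -0.39 against a simulated -0.45, and the covariance -0.174 against -0.054. In 100 random regroupings of the 9 libraries, r ran from -0.91 to 0.37 in the central 95%, a range that holds the observed value. No gene was called in MPX minus CPX, so the planned share of called genes going back could not be given. For EA minus CPX and MPX minus CPX, which share the CPX libraries, r was 0.23 (covariance 0.076) against a simulated 0.50 (covariance 0.130), and 0 genes were called in both by edgeR. DESeq2 called 3 genes in both, 2 higher and 1 lower, where simulated unchanged groups with the same shared libraries gave 1.90 and 0.75 on average (at most 9 and 3). Groups of 3 cannot be halved with 2 libraries in each part, so part of these values may come from the shared libraries.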

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

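The fit without CPX 4 and 6, the B cell index as a covariate, and the list tests on only the groups compared were chosen after seeing the data. Counts of genes past the threshold stayed at 0 in all 3 comparisons with median-ratio or upper-quartile factors, no filter, the stricter filter, limma voom, the robust option off and a minimum change of 2-fold. The filters removed no gene, and the minimum change only selects among the main calls, of which there were 0. Neither therefore says anything about stability. DESeq2 gave 49, 201 and 5 genes for EA minus MPX, MPX minus CPX and EA minus CPX, with 3 genes shared by the last pair, against averages of 16.9, 16.4 and 16.6 genes in 100 simulations of unchanged groups. EA and MPX alone gave 84 genes, and 80 with CPX 4 and 6 left out. With each library left out, the counts ran from 0 to 23 (without CPX 6) for EA minus MPX, 0 to 168 (without CPX 8) for MPX minus CPX and 0 to 12 (without CPX 6) for EA minus CPX. Lists past the threshold ran from 10 to 19, 12 to 17 and 7 to 13 in the same order, and were 0 in every comparison with an estimated correlation and with fry. With CPX 4 and 6 left out, 7 lists passed in EA minus CPX. The opposition of the differences ran from -0.87 to -0.39. The overlap with a library left out says nothing about stability, since each such fit had 0 calls in at least 1 of the 2 comparisons. Of 37 list calls, 13 were kept in all 9 fits with a library left out, and 9 of these 13 also with CPX 4 and 6 left out. That fit leaves CPX 8 alone in its group, with its spread assumed like that of the other groups, so its p-values for CPX compare with 1 library. Genes below the listed level were not analysed here. Except for fewer samples in the fits that leave libraries out, the cause was not tested.

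The covariate is the mean log2 CPM of 10 B cell genes, which are themselves among the genes tested, and it was added after the B cell difference had been seen. With it, edgeR called 584 genes in EA minus MPX, 29 in MPX minus CPX and 540 in EA minus CPX. The covariate was 6.29, 6.94 and 7.99 in EA, 0.92, 1.23 and 0.02 in MPX, and 1.04, 8.85 and 2.05 in CPX 4, 6 and 8. It did not overlap between EA and MPX, so its slope rests largely on CPX 6, and the adjusted differences are extrapolations. Of 191 named gene and comparison pairs, 39 changed sign with the covariate, 7 of them past the threshold, and 12 changed sign with CPX 4 and 6 left out, 0 of them past the threshold. Under the alternatives fixed before the data were examined, 19 pairs changed sign in at least 1. In EA minus MPX with the covariate, the log2 differences that changed sign and passed were those of Adipoq (2.19), Pparg (2.14) and Slc2a4 (2.47). Those that changed sign without passing were Lep 0.51, Bmp3 1.17, Npr3 0.75, Siglec1 -0.092, Lyz2 -0.44, H2-Ob -0.45, Ciita -1.70, H2-Eb1 -1.08, Cd74 -1.46, Cd79b -0.067, Cr2 -0.026, Lox 0.58, Sparc 0.40, Egfl7 0.13, Esam 0.52, Manf -0.02, Hsp90b1 -0.24, Scd1 0.87 and Col1a1 0.13. In MPX minus CPX with the covariate they were Slc25a20 -0.024, H2-Ob 0.26, Ciita 1.01, H2-Aa 0.15, H2-Eb1 0.29, Pax5 0.02, Adipoq -0.70 and Slc2a4 -0.81. In EA minus CPX with the covariate, G0s2 (1.74), Adipoq (1.49), Pparg (0.98) and Slc2a4 (1.66) changed sign and passed, while Bscl2 0.41, Ndufb9 0.046, Cxcl13 -0.53, Pmp22 0.58 and Fasn 0.019 changed sign without passing. The cause was not tested.

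With CPX 4 and 6 left out, the lists that turned direction were the ribosomal list in MPX minus CPX (adjusted p = 0.498) and, in EA minus CPX, the lipolysis (0.70), respiratory chain (0.198), extracellular matrix (0.000494), endothelial (0.0824) and ribosomal (2.44e-13) lists. The named genes were Slc2a4 in MPX minus CPX (-0.10) and, in EA minus CPX, Plin4 -0.19, Ighd 6.35, Robo4 -0.045, Tie1 -0.045, Flt1 -0.26, Rpl37 0.22, Rps12 0.30, Rpl26 0.37, Rpl27 0.41, Lep -0.77 and Col1a1 -0.31. With limma voom the sign changed for Fasn in EA minus MPX (-0.14), for Pparg (0.14) and Scd1 (0.28) in MPX minus CPX, and for G0s2 (0.23), Ighd (2.83), Adipoq (0.083) and Slc2a4 (0.33) in EA minus CPX. With upper-quartile factors it changed for Scd1 in MPX minus CPX (0.047) and Slc2a4 in EA minus CPX (0.013).

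With each library left out, adjusted p ran from 0.000349 to 0.951 for the triglyceride list in MPX minus CPX. In EA minus CPX it ran from 2.39e-06 to 0.234 for lipolysis, 2.24e-09 to 0.589 for fatty acid oxidation, 9.39e-11 to 0.00581 for the respiratory chain and 0.000587 to 0.956 for endothelium. The log2 differences in EA minus MPX ran from -0.83 to 0.49 for Fasn, -0.29 to 0.088 for Slc2a4, -0.29 to 1.31 for Adgre1 and -0.64 to 0.36 for Col1a1. In MPX minus CPX they ran from -2.61 to 0.091 for mt-Co2, -3.50 to 0.28 for Ciita, -0.41 to 1.15 for Adipoq, -0.87 to 0.43 for Pparg, -0.49 to 0.34 for Scd1, -0.49 to 0.69 for Slc2a4 and -0.17 to 1.19 for Adgre1. In EA minus CPX they ran from -0.88 to 0.066 for Bscl2, -0.016 to 0.91 for Plin2, -1.03 to 0.71 for G0s2, -1.69 to 6.17 for Ighd, -0.92 to 1.23 for Cxcl13, -0.67 to 0.66 for Lep, -1.08 to 0.45 for Adipoq and -0.63 to 0.53 for Slc2a4.

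Only the numbers 5 and 7 occur in both EA and MPX. With the number as a block on those libraries edgeR called 160 genes, against 331 for the same libraries without the block. Fasn (-0.14) and Slc2a4 (0.11) changed sign with the block, and Slc2a4 (0.10) and Col1a1 (0.013) without it. The deviations of same-numbered libraries correlated at 0.022 (number 5) and 0.125 (number 7), and those of crossed numbers at 0.217 and 0.407, so the numbers were not taken to pair the libraries.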

Other observations

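The tests given here were chosen after the results were seen, except the counts of lists in other splits and the comparison of CPX 4 with CPX 8 by adipocyte share. Among them, the carry-over measure and the length test of CPX 4 were redefined after first values: the carry-over measure first counted genes over 2-fold either way, and the length test first covered 3 lists at once, with no change of verdict for carry-over. After their values were seen, 2 verdicts were also changed to open: length for the ribosomal list, which had not stood out before the correction, and dilution for the fat mass genes, whose limit was raised from 2 SE to 2.78 SE, the 95% limit of t for 3 libraries per group.

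Antibody genes did not all follow the B cell genes. Ighm, the heavy chain of IgM, was present in MPX at 458.7, 1198 and 1026 CPM and in EA at 668.7, 835.6 and 2030 CPM, a log2 difference of 0.40 (SE 0.65), while Igkc, a light chain, was at 20.9, 8.80 and 11.7 CPM in MPX and at 969.9, 425.5 and 3461 CPM in EA. Oxtr, the oxytocin receptor, was at 28.7, 425.4 and 201.2 CPM in MPX 2, 5 and 7 and at most 22.1 CPM in the other 6 libraries (edgeR adjusted p = 0.775 for EA minus MPX). Ighm, Igkc and Oxtr were singled out here after their values were seen. Antibody segments with close relatives are uncertain because their reads could be split (the B cell list in EA minus CPX had an adjusted p from 1.03e-19 without CPX 6 to 0.886 without CPX 4).

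B cell genes were higher in the 3 EA libraries than in the 3 MPX libraries, and highest in CPX 6. The summed CPM of 10 B cell genes was 795.8, 1263 and 2646 in EA, 40.4, 29.2 and 17.1 in MPX, and 42.7, 5132 and 190.2 in CPX 4, 6 and 8 (exact two-sided permutation p = 0.1 for EA against MPX, the smallest possible). Carry-over of reads from CPX 6 would give 1 ratio to CPX 6 in each EA library. Of 22 genes abundant in CPX 6 and near 0 in MPX, 5 (EA 5), 8 (EA 7) and 3 (EA 8) lay under 1/2 of the median ratio, at least 13.6%. All 5 in EA 5 were antibody genes, with the segments Igkv6-15 at 0.014 and Igkv10-96 at 0.026 against a median of 16.7%. Splitting of reads would act alike on CPX 6 and on reads carried over from it. Those in EA 8 lay close under the limit (0.198 to 0.217, median 45.9%), while Slpi (1.457) and Ighg2c (0.912) lay far above that median. In EA 7 Slpi (0.0036) and Jchain (0.0498) lay far under the median of 19.6%. The values thus argue against carry-over as the only source in EA 5 and EA 7, and less clearly in EA 8. Tissue of about the composition of CPX 6 in the sampled fat may account for part. Its share was set by the B cell genes at 17.6%, 25.4% and 53.6% in EA 5, 7 and 8. Added to the MPX mean at that share, it removed 31.3% (EA 5), 59.7% (EA 7) and 65.1% (EA 8) of the squared log2 difference. This was taken over 3929 genes outside the B cell and class II lists and the 22 genes above, and other genes high in CPX 6 stayed in. At the same shares CPX 8 removed 14.7%, 13.5% and 15.1%, and CPX 4 5.20%, -18.5% and -23.5%. Both held few B cell transcripts, so they are a weak comparison for B cell-rich tissue. An effect of electroacupuncture stays open and cannot be told apart from such tissue, because CPX 6, which had none, held 3.27 times the EA mean. An effect of diet cannot be told apart either, since the labels do not say whether MPX had the high-fat diet of EA.

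All 9 fat mass expansion genes had negative differences in EA minus MPX, but 0 passed when adjusted over the list alone. The camera call was lost with an estimated correlation (adjusted p = 0.628), and EA 7 (0.785) lay beside MPX 2 (0.836). The list lay below the level that dilution by B cell-rich tissue gave (observed minus mixed -1.71 on the log2 scale, SE 0.72, n = 3), with -2.04 in EA 5, -0.53 in EA 7 and -2.56 in EA 8. The EA 7 gap is within the SD of MPX (0.66), and the mean lay 2.38 SE below 0, short of the limit of 2.78, so dilution as the whole cause cannot be told apart from a further change. Observed and mixed levels lay closer in EA 5, 7 and 8 for the adipocyte list (0.21 and 0.13, 0.14 and 0.026, -0.49 and -0.42). The same held for the ribosomal list (-0.27 and -0.082, 0.046 and 0.096, 0.55 and 0.60). For the fat mass list, an effect of electroacupuncture stays open, as 1 library without it, CPX 6 (-3.06), lay below the EA mean (-0.55). The list was not lower in EA than in CPX, whose mean was -0.99, with CPX 4 at -0.335 and CPX 8 at 0.419. In EA minus CPX its median log2 difference was 0.027, with 5 of 9 genes positive. An effect of electroacupuncture also cannot be told apart from chance between 3 libraries. An effect of diet cannot be told apart either, since the labels do not say whether MPX had the high-fat diet of EA.

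CPX 4 was high in mitochondrially encoded, respiratory chain and ribosomal protein genes, and shorter genes stood higher in it (Spearman's correlation with length -0.46 across genes, which are not independent replicates). The ribosomal list was 1.73 SD above the other 8 libraries before and 0.69 SD with the length trend removed, so length cannot be told apart from other causes there. The respiratory chain list stayed 3.86 SD above (5.50 before) and kept 52.7% of its deviation, which argues against length as its whole cause. The mitochondrially encoded list stayed 2.49 SD above but kept only 49.1% of its deviation, so length cannot be told apart from another cause there. The shares kept by these lists are close, and the limit between them was chosen after the results were seen. The excess of CPX 4 over CPX 8 in the ribosomal list exceeded that in the adipocyte list by 0.955 (SE 0.149 across genes), short of the limit of 1 fixed beforehand. A larger share of adipocytes in CPX 4 thus stays open for the ribosomal list, although that share alone would give no such excess. The ribosomal list was as high in CPX 6 (1.16, against 1.07), where length correlated at 0.15 and the adipocyte list was lowest (-2.03), so a high level also occurs without a short-gene bias and with few adipocyte transcripts, though 1 library excludes neither explanation. Apart from the adipocyte share, no biological explanation was tested for CPX 4.

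The splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For genes past the threshold the real count was 0 and the highest other 0 in each comparison, so 10 of 10 splits gave as many, which a real count of 0 fixes beforehand. For lists in EA minus MPX the real count was 10 and the highest other 18, with 10 splits giving as many. In MPX minus CPX the real count was 15 and the highest other 21, with 6 splits giving as many, and in EA minus CPX 12 and 22, with 8 splits.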
